A study of Candida albicans with 9 samples.

How the data were processed

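The series holds 9 RNA sequencing libraries of Candida albicans SC5314, 3 biological replicates each of a drug-free control, fluconazole and NT-a9. Per the labels' protocols, overnight cultures were set to 2000000 cells per mL and shaken at 200 rpm and 30 °C for 12 h, with either compound at 4 times the minimum inhibitory concentration. Per the labels' protocols, mRNA was captured with oligo(dT) beads and sequenced on a DNBSEQ-T7 instrument. The authors deposited 1 table of FPKM values, with 6205 genes and 1 column per library. Per the submitters' processing notes, CASAVA, HISAT2 and featureCounts were used, with neither versions nor roles given. The genome build, the annotation, the strand setting of the counting and the lengths behind FPKM are not given in the sources used here.

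Gene names came from a table of RefSeq genes of the assembly ASM18296v3, in which all 6205 locus tags were found and 2938 had a symbol. Since no build is stated for the deposited table, no coordinates are given, and that table served only for names, classes of RNA and lengths. Its lengths are annotated spans, which for protein-coding genes are nearly all multiples of 3 and so hold no untranslated regions. They are called coding length below, although spans of genes with introns are longer than that and RNA genes have only a span.

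Fragments per library were recovered from the steps between low FPKM values, which are whole multiples of the value of 1 fragment. With the annotated span as length, 93.8% of values came out whole within 0.001 fragments, and 420 genes needed a shorter length. The recovered fragments summed to between 100.02 and 100.06% of the totals that the steps gave, which ran from 33091185 to 62428664 per library. In these libraries 3 fragments on a gene of 1 kb correspond to between 0.0481 and 0.0907 FPKM. This floor covers counting error only, since reads without molecular identifiers are not independent molecules. Between replicates, recovered fragments varied 49.4 to 352 times as much as counting error allows (chi-square per degree of freedom over all genes, to which abundant genes add most). The median standard error of a log2 fold change was 0.169, and the median 95% confidence half-width 0.361.

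The values were used as deposited, as log2(FPKM + 1), for the 5913 genes with at least 1 FPKM in at least 3 libraries. A linear model with 1 mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, which left 6 residual degrees of freedom. The 3 comparisons were fluconazole against control, NT-a9 against control and NT-a9 against fluconazole. Tests were two-sided with Benjamini-Hochberg adjustment over the 5913 genes within a comparison, and a gene was called at an adjusted p below 0.05. "Rose" and "fell" are used for called genes only.

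The 31 gene lists were ergosterol biosynthesis, drug efflux, iron acquisition, copper and zinc homeostasis, cell wall, hyphal growth and adhesion, white and opaque cell markers, secreted proteases and lipases, oxidative stress, heat shock and protein folding, and osmotic stress and glycerol. Further lists were glycolysis and ethanol fermentation, gluconeogenesis and glyoxylate cycle, tricarboxylic acid cycle, oxidative phosphorylation, alternative oxidase, fatty acid synthesis, fatty acid beta-oxidation, sphingolipid synthesis, amino acid biosynthesis, and sulfur assimilation and methionine. The remaining lists were sugar transport, amino acid and peptide transport, glycogen and trehalose, cytosolic ribosomal proteins, ribosome biogenesis, proteasome, DNA replication and cell cycle, histones, autophagy and vacuole, and calcium and calcineurin signalling. Of the 781 symbols fixed over the lists, 52 were not in the table. Lists with at least 3 tested genes, which leaves out alternative oxidase, were tested with camera at a preset correlation of 0.01 between genes. Camera with the correlation estimated from the data, fry and the count of calls adjusted over the list alone stand beside it.

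Named genes followed a rule. In each comparison it took the 8 called genes with the highest and the 8 with the lowest log2 fold change, among those with a symbol, a group mean of at least 10 FPKM and no overlap between the groups. It added from each list up to 4 called members with the largest change, or the 2 highest where none was called, and ERG11, ERG3, UPC2, CDR1, CDR2 and MDR1 in every comparison. ERG1, ERG6, ERG10, ERG4 and MVD of the ergosterol list, and DRE2, HAC1, COX17 and the genes of the closing paragraphs on shared symbols, fall outside it in at least 1 comparison and were chosen after their values were seen.

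The groups, tests, lists, naming rule and most alternatives were set before the data were examined. Alternatives set then were pseudocounts of 0.1 and 5, no filter or a minimum of 10 FPKM, quantile normalization, median-of-ratios scaling, no trend, only the 6 libraries compared, the replicate number as a block, each library left out in turn, a 2-fold minimum, and the other list tests. Voom weights on the recovered fragments, protein-coding genes only, rescaling without ribosomal RNA or without the 100 most abundant genes, and the sphingolipid list without LIP1 were added after seeing the data.

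The similarity of both treatments was set beside 100 simulations of unchanged groups sharing the 3 controls. The scripts were tested on simulated data for fluconazole against control with 5771 genes, 200 of them changed. They recovered 28.6% of genes changed by 0.5 on the log2 scale, 95.9% of those changed by 1 and all of those changed by 2 or 4, and 10 unchanged genes were among 170 called. A shifted ergosterol list was called and 0 of the 30 lists was called besides it. The simulated genes varied independently, so this does not show how often camera calls unchanged lists of correlated genes. Depth recovery and figures used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.

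Because the strand setting is not stated, values of overlapping and antisense genes are uncertain. The same holds for genes with near-identical copies, among them the ALS, SAP, HGT, TLO, SSA, histone and ribosomal RNA genes, since it is not stated how shared reads were counted. With groups of 3 libraries no test of single outlying libraries was run, and no library was left out of the main fit.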

Results

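RNA was sequenced from Candida albicans SC5314, a yeast that can cause thrush and bloodstream infections, after 12 h without drug, with fluconazole or with NT-a9. Fluconazole is an azole antifungal that inhibits Erg11, an enzyme of ergosterol synthesis. NT-a9 is known here only by its code name. Both compounds were given at 4 times the minimum inhibitory concentration, and no concentration is stated, so the doses match only on that scale. Each of the 3 groups held 3 biological replicates, and each replicate gave 1 library. The fragments behind the table came to 41854373, 45449004 and 39777426 in the control libraries, 48839686, 37240807 and 33091185 in the fluconazole libraries and 62428664, 43258860 and 45121725 in the NT-a9 libraries. Gene levels are FPKM (fragments scaled to gene length and library total) and are given as mean ± SD over the 3 libraries of a group (n = 3). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and adjusted p-values are from limma over 5913 genes.

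Across genes, libraries of 1 group correlated at 0.993 to 0.994 in control, 0.990 to 0.993 with fluconazole and 0.982 to 0.994 with NT-a9 (Pearson's r over genes, which are not independent replicates). Fluconazole and control libraries correlated with each other at 0.986 to 0.992, and NT-a9 and control libraries at 0.838 to 0.861. The first principal component held 87.2% of the variance and placed the NT-a9 libraries at 64.3 to 67.3 and the other 6 libraries at -36.8 to -30.2. Ribosomal RNA took 4.997% ± 2.56 of fragments in control, 1.67% ± 0.428 with fluconazole and 1.21% ± 0.235 with NT-a9 (SD, n = 3), and the control libraries ranged from 2.96 to 7.87%. The 100 genes highest over all libraries took 48.0% ± 1.79 of fragments in control, 47.9% ± 0.715 with fluconazole and 36.9% ± 1.29 with NT-a9 (SD, n = 3). The metallothionein gene CUP1 alone took 1.39% ± 0.149 in control, 1.40% ± 0.198 with fluconazole and 0.639% ± 0.0671 with NT-a9 (SD, n = 3).

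Fluconazole against control asks which genes differ after 12 h with the azole. 9 genes of ergosterol synthesis rose with fluconazole. ERG24 (CAALFM_C209400CA), a sterol reductase of the pathway, stood at 20.6 ± 1.16 against 8.82 ± 0.531 FPKM (SD, n = 3), a log2 fold change of 1.14. ERG13 and HMG1, which encode the synthase and the reductase of hydroxymethylglutaryl-CoA early in the pathway, rose by 0.90 and 0.82 on the log2 scale. PGA10 (CAALFM_C400450CA), a cell-surface haem receptor, rose most, at 223 ± 54.8 against 72.03 ± 11.5 FPKM (SD, n = 3), a log2 fold change of 1.60. In all, 17 genes rose and 43 fell.

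Of the 25 ergosterol genes, 9 rose, none fell and 16 did not pass the test, and 12 rose when adjusted over the list alone. Besides the 3 above, ERG27 rose by 0.84 (limma, adjusted p = 0.0201), ERG7 by 0.78 (adjusted p = 0.0201), ERG5 by 0.73 (adjusted p = 0.0271), ERG1 by 0.70 (adjusted p = 0.0329), ERG10 by 0.69 (adjusted p = 0.0297) and ERG6 by 0.69 (adjusted p = 0.0329). ERG11, which encodes the target of fluconazole, stood at 62.8 ± 9.83 against 40.3 ± 4.35 FPKM (SD, n = 3), a log2 fold change of 0.62 that did not pass (limma, adjusted p = 0.141). Its fluconazole libraries (56.0 to 74.1 FPKM) all lay above its control libraries (35.6 to 44.2 FPKM), and 27.0% of all genes did not overlap between these groups. The standard error draws on all 9 libraries, and ERG11 spread most in the NT-a9 libraries (555, 960 and 555 FPKM). The missed call therefore does not show that ERG11 was unchanged. UPC2, the transcription factor that activates ergosterol genes, stood at 9.5 ± 0.678 against 7.12 ± 0.783 FPKM (adjusted p = 0.292). The sterol desaturase gene ERG3 stood at 72.2 ± 14.1 against 46.5 ± 3.75 FPKM (adjusted p = 0.288). Its standard error of 0.268, against a median of 0.169 over all genes, draws on the NT-a9 libraries too. The drug pump genes CDR1, CDR2 and MDR1 had log2 fold changes of -0.14, 0.06 and -0.11 (adjusted p = 0.8201, 0.902 and 0.824), and none of the 18 drug efflux genes passed. The list test camera called the ergosterol list higher (adjusted p = 3.46e-18), with adjusted p = 0.255 with an estimated correlation.

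**Figure D1:**
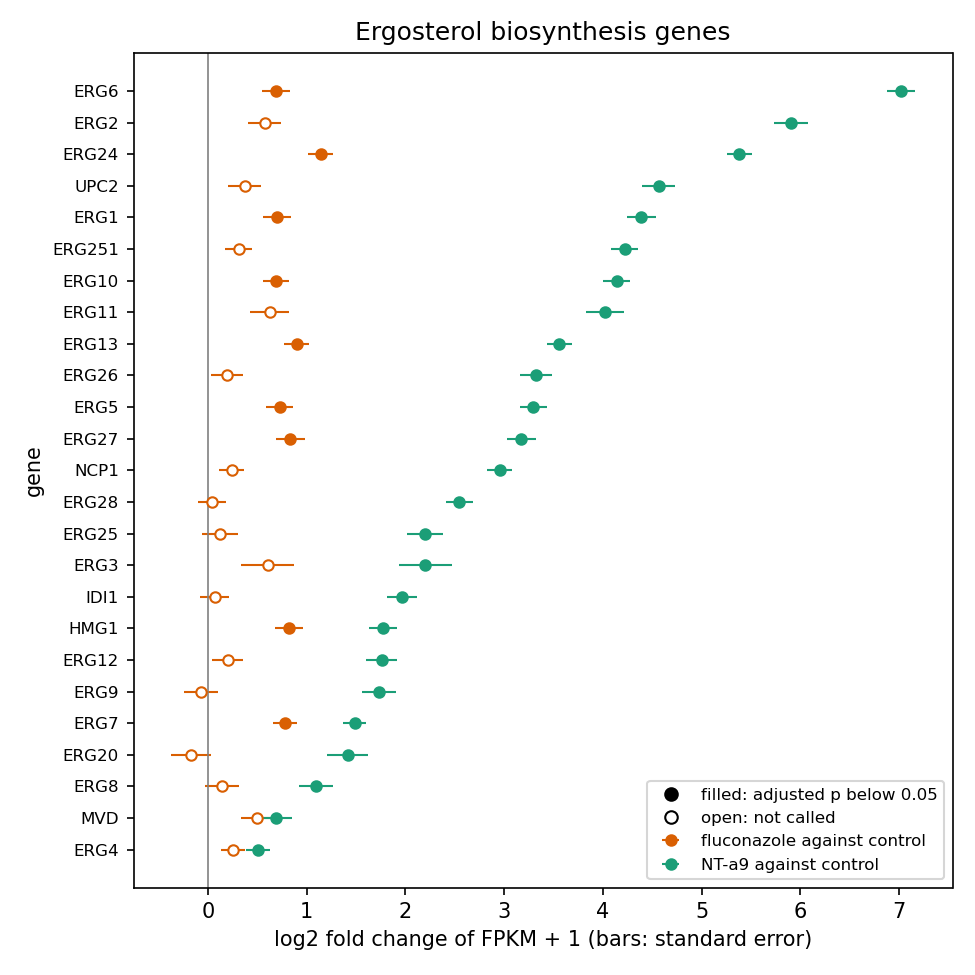
Log2 fold change of each of the 25 ergosterol biosynthesis genes against control on the log2(FPKM + 1) scale, for fluconazole and for NT-a9, with the standard error from limma as bars (3 libraries per group); filled points passed the test. All 25 genes lie above 0 with NT-a9 (23 pass after median-of-ratios scaling and 24 after quantile normalization), and 9 pass with fluconazole.

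Besides PGA10, the iron acquisition list held 1 further riser, PGA7, another haem-binding surface protein, at 1219 ± 73.9 against 746 ± 92.2 FPKM (SD, n = 3), so that 2 of its 26 genes rose and 4 did when adjusted over the list alone. The catalase gene CAT1 rose by 0.63 as 1 of 33 oxidative stress genes, and the acetyl-CoA synthetase gene ACS2 by 0.75 as 1 of 12 genes of gluconeogenesis and the glyoxylate cycle. The genes that fell were 39 protein-coding, 2 ribosomal RNA and 2 small nucleolar RNA genes. The ribosomal RNA genes were RDN25 (-1.56) and RDN18 (-1.47), neither of which passed with median-of-ratios scaling. After oligo(dT) capture the share of ribosomal RNA ranged from 2.96 to 7.87% within the control libraries alone. SPC19, a kinetochore protein, stood at 8.93 ± 3.04 against 19.8 ± 0.794 FPKM (SD, n = 3), and the arginase gene CAR1 at 8.25 ± 1.05 against 17.1 ± 3.46 FPKM. The translation initiation factor gene SUI1 stood at 191 ± 49.9 against 354 ± 13.03 FPKM and the transcription regulator gene TRY6 at 19.7 ± 4.2 against 41.9 ± 3.12 FPKM. RPS27A, at 37.5 ± 6.75 against 72.5 ± 9.37 FPKM, was the 1 gene of 67 cytosolic ribosomal protein genes to fall, and none rose. In each of the other 26 lists no gene passed over all genes tested, while 934 of all 5913 genes had an unadjusted p under 0.05 in limma. Adjusted over the list alone, 3 white and opaque cell marker genes, 2 osmotic stress genes and 1 sugar transport gene fell, and 2 genes of the tricarboxylic acid cycle rose. Likewise 2 genes of oxidative phosphorylation rose and 1 fell, and in sphingolipid synthesis and in DNA replication and cell cycle 1 rose and 1 fell each.

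Camera called 11 further lists higher, although at most 2 genes of each had passed over all genes tested. These were iron acquisition, gluconeogenesis and glyoxylate cycle (adjusted p = 0.00165 each), cytosolic ribosomal proteins (adjusted p = 2.95e-05), oxidative phosphorylation (adjusted p = 4.52e-05) and tricarboxylic acid cycle (adjusted p = 1.07e-04). The rest were cell wall (adjusted p = 0.005003), glycolysis (adjusted p = 0.0133), amino acid biosynthesis and ribosome biogenesis (adjusted p = 0.01401 each), hyphal growth (adjusted p = 0.0141) and heat shock (adjusted p = 0.0372). The proteasome list was called lower (adjusted p = 0.0343). With an estimated correlation these 12 lists ran from adjusted p = 0.485 to adjusted p = 0.716, so none held. Fry, which tests whether the genes of a list move on balance 1 way, called the ergosterol list higher (adjusted p = 0.0133) and the white and opaque cell marker list lower (adjusted p = 0.003297). The latter list holds markers of both cell forms, so its direction does not tell which form prevailed. Camera calls that ended when 1 library was left out were those of amino acid biosynthesis (without control or fluconazole replicate 3, adjusted p up to 0.0658), cell wall (without fluconazole replicate 3, adjusted p = 0.0766) and ribosome biogenesis (without control replicate 2 or fluconazole replicate 1, adjusted p up to 0.0546). So did those of heat shock (without control replicate 2 or fluconazole replicate 1 or 2, adjusted p up to 0.252) and of hyphal growth and the proteasome (without control replicate 1 or fluconazole replicate 3, adjusted p up to 0.184 each).

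The 60 calls depended on single libraries: 12, 13 and 5 genes passed without control replicate 1, 2 and 3, and 34, 7 and 2 without fluconazole replicate 1, 2 and 3, while 178 passed without NT-a9 replicate 2. PGA10 and ERG24 kept their calls under all 9 omissions, and 21 of the 23 called genes followed through the omissions lost theirs under at least 1, with a highest adjusted p between 0.0565 (ERG13, without fluconazole replicate 3) and 0.198 (HAC1, without control replicate 1). Of the 60 calls 28.3% were higher, against 50.9% of 55 with median-of-ratios scaling (28 higher, 27 lower) and 17.1% of 111 when the values were rescaled without ribosomal RNA (19 higher, 92 lower).

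NT-a9 against control asks which genes differ after 12 h with NT-a9. No culture density is given, so in every list below a response to the compound cannot be told apart from a difference in growth stage. All 25 ergosterol genes rose, as did 66 of 67 genes of cytosolic ribosomal proteins and 44 of 57 of amino acid synthesis, while 15 of 20 sugar transport genes fell. ERG6 (CAALFM_C302150CA), a sterol methyltransferase, stood at 2332 ± 208 against 17.03 ± 2.91 FPKM (SD, n = 3), 137 times the control level. PGA13 (CAALFM_CR08510WA), a cell wall protein, stood at 2357 ± 511 against 11.8 ± 0.323 FPKM (SD, n = 3), 199 times the control level. The glucose transporter gene HGT6 (CAALFM_C201020WA) fell from 4802 ± 329 FPKM to 72.99 ± 15.4 FPKM (SD, n = 3), and HSP31 (CAALFM_C102070WA), of the heat shock list, from 3599.6 ± 558 FPKM to 21.8 ± 4.02 FPKM.

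In all, 2749 genes rose and 1552 fell with NT-a9 (limma), and 1596 and 694 of them changed at least 2-fold. The median gene lay at 0.30 on the log2 scale, and median-of-ratios scaling, which sets it to 0.01, gave 2145 higher and 2216 lower, so that the higher share went from 63.9 to 49.2%. The medians of the ergosterol, ribosomal protein and sugar transport lists are therefore also given relative to the median gene. Counts after that scaling are given where it moves a list's majority.

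In the ergosterol list the median log2 fold change was 2.95, 2.65 above the median gene. For the ergosterol list camera gave adjusted p = 4.77e-09, and adjusted p = 0.552 with an estimated correlation. The sterol isomerase gene ERG2 stood at 452 ± 51 against 6.63 ± 1.54 FPKM (SD, n = 3), ERG24 at 409 ± 32.8 against 8.82 ± 0.531 FPKM and ERG11 at 689.9 ± 234 against 40.3 ± 4.35 FPKM. UPC2, the activator of the pathway, stood at 194 ± 40.99 against 7.12 ± 0.783 FPKM (limma, adjusted p = 1.32e-11). ERG3 rose by 2.20 with a wide spread, at 238 ± 130.2 against 46.5 ± 3.75 FPKM (SD, n = 3). Drug efflux genes went both ways, with 6 of 18 higher and 7 lower. The pump genes MDR1 and QDR1 rose by 2.22 and 2.48, and CDR4, CDR11 and CDR2 fell, with log2 fold changes of -2.72, -1.72 and -0.80. CDR1 stood at 480.5 ± 179.6 against 428 ± 37.7 FPKM (SD, n = 3) and did not pass (limma, adjusted p = 0.728), but rose by 0.44 without NT-a9 replicate 2.

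**Figure D2:**
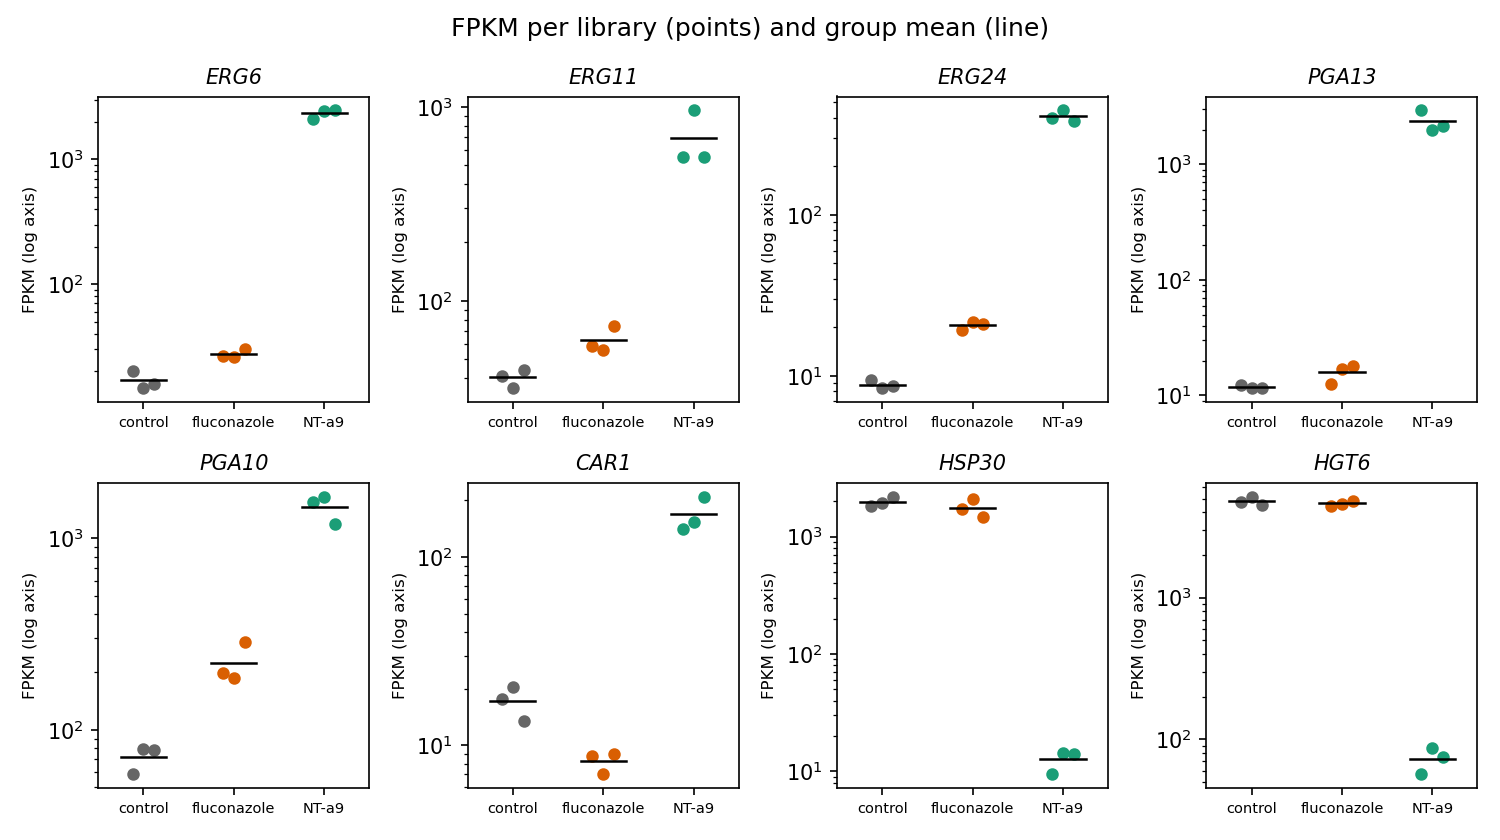
FPKM of 8 genes in each of the 9 libraries (points, log axis) with the mean of each group (lines). For each of the 8 genes the 3 NT-a9 libraries lie apart from the 6 others, higher for ERG6, ERG11, ERG24, PGA13, PGA10 and CAR1 and lower for HSP30 and HGT6.

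Of 40 cell wall genes, 23 rose and 8 fell, among them the risers PGA31, a wall protein (64.6 ± 6.27 against 1.04 ± 0.153 FPKM; SD, n = 3), and the chitin synthase gene CHS2 (94.1 ± 30.05 against 3.67 ± 0.215 FPKM). RHD3, another wall protein, fell, at 94.5 ± 9.23 against 1483 ± 40.8 FPKM. GFA1, the enzyme that opens chitin precursor synthesis, and the surface protein gene PGA45 lie outside the list and rose by 5.73 and 5.01. In the list of hyphal growth and adhesion, 9 of 23 rose and 9 fell (8 and 10 with median-of-ratios scaling), with the surface superoxide dismutase gene SOD5 at 49.8 ± 5.08 against 0.755 ± 0.199 FPKM. The hyphal wall gene HWP1 stood at 35.9 ± 8.63 against 2.704 ± 0.437 FPKM and RBR3 at 10.6 ± 3.94 against 61.03 ± 2.18 FPKM. Among 9 white and opaque cell markers, 4 rose and 2 fell, but 2 rose and 5 fell with median-of-ratios scaling. The marker of the white form, WH11, and the protease gene SAP3 fell, with log2 fold changes of -1.80 and -1.96, and PBR1 and WOR2 rose by 4.15 and 1.16. Of 18 secreted proteases and lipases, 8 rose and 5 fell (6 and 6 with median-of-ratios scaling), with LIP8 higher by 2.80 and LIP1 at -1.97. None of these 4 lists was called by camera on the deposited scale (adjusted p = 0.101, 0.356, 0.734 and 0.996 in this order). The cell wall list was called higher with quantile normalization (adjusted p = 0.0313).

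Of 26 iron acquisition genes, 18 rose and 4 fell (16 and 7 with median-of-ratios scaling; camera, adjusted p = 0.107). PGA10 stood at 1458 ± 242 against 72.03 ± 11.5 FPKM (SD, n = 3). The vacuolar iron transporter gene FTH1 stood at 126 ± 14.7 against 6.098 ± 0.7895 FPKM and the ferroxidase gene FET34 at 122 ± 4.21 against 12.1 ± 1.64 FPKM. The iron list also holds CFL4, a ferric reductase gene, which rose by 2.94. Of 10 copper and zinc genes, 4 rose and 4 fell (3 and 5 with median-of-ratios scaling; camera, adjusted p = 0.431). The metallothionein gene CUP1 fell, at 62671 ± 6581 against 136615 ± 14582 FPKM (SD, n = 3) and the copper transporter gene CTR1 at 4335 ± 729.9 against 8586 ± 559 FPKM. CRD2, another metallothionein, rose by 1.98 and the zinc scavenger gene PRA1 by 1.004. CUP1 is the highest gene in every library, so quantile normalization sets its change to 0, and PRA1 did not pass under it.

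Of 67 cytosolic ribosomal protein genes, 66 rose and 1 did not pass, with a median of 2.15, 1.85 above the median gene. For the ribosomal protein list camera gave adjusted p = 1.03e-14, and adjusted p = 0.552 with an estimated correlation. RPS14B stood at 3518 ± 429 against 367 ± 50.9 FPKM (SD, n = 3) and RPS20 at 1963 ± 295 against 226 ± 38.6 FPKM. Of 72 ribosome biogenesis genes, 61 rose and 3 fell, with SIK1 at 237 ± 48.8 against 44.1 ± 6.26 FPKM and PWP2, which went the other way, at 24.7 ± 1.86 against 188 ± 10.8 FPKM. For the ribosome biogenesis list camera gave adjusted p = 1.23e-05, and adjusted p = 0.552 with an estimated correlation. Of 57 amino acid biosynthesis genes, 44 rose and 5 fell. For the amino acid list camera gave adjusted p = 1.46e-05, and adjusted p = 0.552 with an estimated correlation. The glutamate dehydrogenase gene GDH3 stood at 2294 ± 259 against 95.8 ± 9.88 FPKM (SD, n = 3). The lysine gene LYS9 stood at 323 ± 40.1 against 21.01 ± 4.04 FPKM and the leucine gene LEU2 at 365 ± 49.98 against 30.7 ± 2.07 FPKM. In the sulfur assimilation and methionine list 14 of 20 rose and none fell, led by the S-adenosylmethionine synthetase gene SAM2 (2.80) and MET15 (2.41); with median-of-ratios scaling 12 rose and 4 fell. For the sulfur list camera gave adjusted p = 0.0312, and adjusted p = 0.552 with an estimated correlation.

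Of 20 sugar transport genes, 15 fell and 2 rose, with a median of -1.70, -2.002 relative to the median gene. For the sugar transport list camera gave adjusted p = 6.95e-07, and adjusted p = 0.3497 with an estimated correlation. HGT2 stood at 96.2 ± 11.9 against 3241 ± 371 FPKM (SD, n = 3). HGT17 stood at 11.3 ± 2.39 against 388 ± 35 FPKM and HGT1 at 80.8 ± 14.8 against 1091 ± 90.5 FPKM. Of 30 amino acid and peptide transport genes, 20 fell and 7 rose. For the amino acid transport list camera gave adjusted p = 1.89e-04, and adjusted p = 0.552 with an estimated correlation. The S-adenosylmethionine permease gene GAP4 stood at 75.4 ± 6.14 against 703 ± 93.9 FPKM and the basic amino acid permease gene CAN2 at 15.8 ± 2.805 against 128 ± 8.5 FPKM (SD, n = 3). The dicarboxylate transporter gene JEN2 and the formate dehydrogenase gene FDH1, outside the lists, fell, at 2.88 ± 0.519 against 387 ± 19.1 FPKM and 80.3 ± 14.7 against 5989 ± 269 FPKM. IFE2, an alcohol dehydrogenase gene, fell, at 180.0 ± 34.3 against 4476 ± 409.6 FPKM.

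Of 21 genes of glycolysis and fermentation, 16 rose and 1 fell. For the glycolysis list camera gave adjusted p = 0.04895, and adjusted p = 0.647 with an estimated correlation. The pyruvate kinase gene CDC19 stood at 3279 ± 302 against 425 ± 46.3 FPKM (SD, n = 3). The glycolytic regulator gene GAL4 stood at 906 ± 30.99 against 160.4 ± 6.297 FPKM and the pyruvate decarboxylase gene PDC11 at 5982 ± 804 against 1645 ± 163 FPKM. Of 12 genes of gluconeogenesis and the glyoxylate cycle, 7 fell and 3 rose. For the gluconeogenesis list camera gave adjusted p = 0.04895, and adjusted p = 0.552 with an estimated correlation. PCK1, FBP1 and ICL1, key enzymes of those routes, fell, with log2 fold changes of -2.35, -1.99 and -1.34, and ACS2 rose by 1.38. Among 13 glycogen and trehalose genes, 6 fell and 1 rose. TPS3 of trehalose synthesis stood at 88.02 ± 14.2 against 501 ± 57.3 FPKM (SD, n = 3) and the glycogen synthase gene GSY1 at 1882 ± 176 against 7636 ± 1149 FPKM. For the glycogen list camera gave adjusted p = 0.0297, and adjusted p = 0.552 with an estimated correlation.

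Among mitochondrial lists, 13 of 22 tricarboxylic acid cycle genes rose and 7 fell (camera, adjusted p = 0.431), with IDP1 higher by 3.50 and LAT1 by 2.92. Of 34 oxidative phosphorylation genes, 18 rose and 6 fell, against 10 and 9 with median-of-ratios scaling (camera, adjusted p = 0.572), and ATP5 and COX13 rose by 1.14 and 0.98. Both alternative oxidase genes, too few for a list test, fell, with AOX2 at 285 ± 49.6 against 3623 ± 968 FPKM (SD, n = 3) and AOX1 at 41.5 ± 7.81 against 85.2 ± 1.42 FPKM. In fatty acid synthesis 9 of 13 rose and 1 fell (camera, adjusted p = 0.252), with the synthase genes FAS1 and FAS2 at 219 ± 29.6 against 63.4 ± 4.87 FPKM and 156 ± 30.2 against 32.8 ± 4.11 FPKM. Of 24 beta-oxidation genes, 9 rose and 8 fell (6 and 9 with median-of-ratios scaling; camera, adjusted p = 0.572), with the thiolase gene FOX3 higher by 1.84 and the carnitine acetyltransferase gene CTN1 at -2.51. Of 16 sphingolipid genes, 9 rose and 3 fell (camera, adjusted p = 0.417), with the ceramide synthase gene LAC1 higher by 2.87 and the desaturase gene SLD1 by 2.72. The symbol LIP1 in that list belongs to a secreted lipase in this species, and without it 9 of 15 rose and 2 fell, with a median of 1.10 (camera, adjusted p = 0.238).

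Of 47 DNA replication and cell cycle genes, 39 rose and 3 fell. For the cell cycle list camera gave adjusted p = 4.70e-05, and adjusted p = 0.552 with an estimated correlation. The ribonucleotide reductase gene RNR1 stood at 65.2 ± 9.501 against 2.86 ± 0.12 FPKM (SD, n = 3) and the cyclin gene PCL1 at 38.2 ± 3.96 against 2.82 ± 0.357 FPKM. Of 11 histone genes, 8 fell and 1 rose, with the linker histone gene HHO1 at 298 ± 63.1 against 817 ± 25.2 FPKM. For the histone list camera gave adjusted p = 0.0231, and adjusted p = 0.679 with an estimated correlation. Of 16 genes of calcium and calcineurin signalling, 13 rose and 1 fell. For the calcium list camera gave adjusted p = 0.0411, and adjusted p = 0.552 with an estimated correlation. The calcium channel gene CCH1 stood at 46.2 ± 10.8 against 7.86 ± 1.42 FPKM and the calcineurin regulator gene RCN1 at 6.99 ± 1.69 against 0.794 ± 0.3102 FPKM (SD, n = 3). Of 24 heat shock and protein folding genes, 9 rose and 10 fell (camera, adjusted p = 0.233). HSP30 stood at 12.6 ± 2.72 against 1974 ± 192 FPKM. The small heat shock gene HSP21 stood at 2256 ± 661 against 13478 ± 1167 FPKM and SSA2, of the Hsp70 family, at 147 ± 26.6 against 6.501 ± 0.861 FPKM.

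Oxidative stress genes divided into 12 higher and 11 lower of 33 (8 and 15 with median-of-ratios scaling; camera, adjusted p = 0.356), with the thioredoxin reductase gene TRR1 higher by 2.26 and OYE22 at -3.06. Of 13 osmotic stress and glycerol genes, 4 rose and 4 fell (3 and 7 with median-of-ratios scaling; camera, adjusted p = 0.572), and the glycerol synthesis genes GPD2 and RHR2 rose by 1.97 and 1.77. Proteasome genes were higher in 16 of 26 and lower in 2 (camera, adjusted p = 0.253), and RPN4, which activates them, stood at 1036 ± 231 against 344 ± 14.7 FPKM (SD, n = 3). Autophagy and vacuole genes were higher in 9 of 19 and lower in 7 (6 and 9 with median-of-ratios scaling; camera, adjusted p = 0.572), with VMA10 of the vacuolar proton pump at 2.07 and the autophagy kinase gene ATG1 at -1.23.

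**Figure D3:**
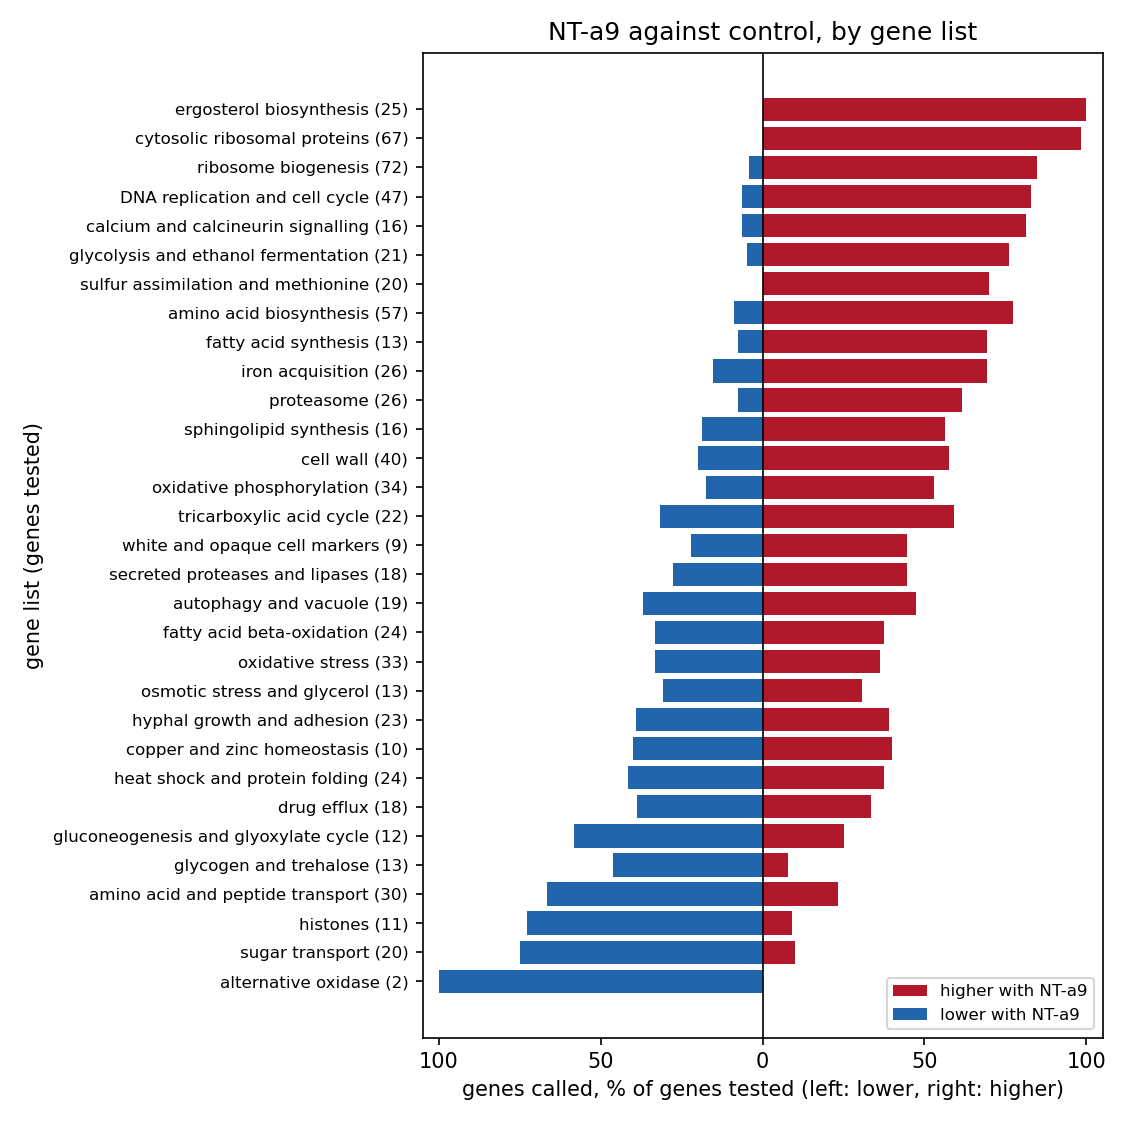
Percent of the tested genes of each list that passed the limma test, higher to the right and lower to the left, for NT-a9 against control (3 libraries each). All 25 ergosterol genes and 66 of 67 cytosolic ribosomal protein genes were higher and 15 of 20 sugar transport genes lower. With median-of-ratios scaling the majority turned from higher to lower for oxidative stress, beta-oxidation, autophagy and white and opaque markers.

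Camera called 13 lists with NT-a9, 8 higher and 5 lower, and none held with an estimated correlation. Fry called 24. Leaving out control replicate 1 ended the camera call of calcineurin signalling. Those of glycolysis and of gluconeogenesis ended in 6 and 7 of the 9 omissions and with median-of-ratios scaling (camera, adjusted p = 0.0885 and 0.0704). The gluconeogenesis call also ended with quantile normalization (camera, adjusted p = 0.121). Among the 138 called genes followed through the omissions, 137 kept their calls in all 9 and SOD5 in the 6 that left it past the filter. Most of these genes were picked for large changes, so they do not stand for all calls. Over all 4301 calls, 3907 (without NT-a9 replicate 3) to 4249 (without fluconazole replicate 3) were kept under single omissions.

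NT-a9 against fluconazole compares the compounds directly at 12 h and 4 times the minimum inhibitory concentration each. ERG6 stood at 2332 ± 208 against 27.8 ± 2.33 FPKM (SD, n = 3), a log2 difference of 6.34 (limma, adjusted p = 1.64e-13), and ERG11 at 689.9 ± 234 against 62.8 ± 9.83 FPKM, a difference of 3.40. Of the 25 ergosterol genes 23 were higher with NT-a9 and none lower, and ERG4 and MVD did not pass, with log2 differences of 0.25 and 0.19. PGA10 was higher with NT-a9 as well, at 1458 ± 242 against 223 ± 54.8 FPKM (SD, n = 3). MDR1 was higher by 2.33 and CDR2 lower at -0.86, and CDR1 at 480.5 ± 179.6 against 387 ± 26.1 FPKM did not pass (limma, adjusted p = 0.359).

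All 67 cytosolic ribosomal protein genes were higher with NT-a9 than with fluconazole (66 with median-of-ratios scaling), with RPS27 at 4524 ± 375 against 451 ± 53.3 FPKM (SD, n = 3). Of 57 amino acid biosynthesis genes 46 were higher and 5 lower. Of 47 DNA replication and cell cycle genes 39 were higher and 3 lower, with RNR22, a ribonucleotide reductase gene, at 263 ± 11.7 against 29.7 ± 2.75 FPKM. Sugar transport genes were lower in 15 of 20 and higher in 3, with HGT6 at 72.99 ± 15.4 against 4616 ± 201 FPKM. Amino acid and peptide transport genes were lower in 18 of 30 and higher in 8. Glycogen and trehalose genes were lower in 8 of 13 and higher in 3, with TPS3 at 88.02 ± 14.2 against 643 ± 26.6 FPKM (SD, n = 3). Gluconeogenesis and glyoxylate genes were lower in 8 of 12 and higher in 3, with PCK1 at 315 ± 31.6 against 1694 ± 608 FPKM. Calcium and calcineurin genes were higher in 13 of 16, sulfur assimilation genes in 14 of 20 and ribosome biogenesis genes in 62 of 72, and 8 of 11 histone genes were lower.

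Over all genes, 2946 were higher and 1357 lower with NT-a9 than with fluconazole (limma). Median-of-ratios scaling gave 2190 and 2180 and takes the median gene from 0.40 to 0.01. Camera called 12 lists. Those higher were ergosterol (adjusted p = 5.01e-07), ribosomal proteins (adjusted p = 5.92e-13), amino acid biosynthesis and ribosome biogenesis (adjusted p = 9.99e-05 each), DNA replication and cell cycle (adjusted p = 2.12e-04), sulfur assimilation and calcineurin signalling (adjusted p = 0.0444 each). Those lower were sugar transport (adjusted p = 5.01e-07), amino acid transport (adjusted p = 2.12e-04), gluconeogenesis (adjusted p = 0.00469), glycogen and trehalose (adjusted p = 0.00747) and histones (adjusted p = 0.0119). With an estimated correlation these 12 ran from adjusted p = 0.325 to adjusted p = 0.778. The calcineurin call ended without control replicate 3 or fluconazole replicate 1, and the sulfur call without control replicate 3 or fluconazole replicate 2 and with median-of-ratios scaling (adjusted p = 0.0880).

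The last comparison sets the responses to both compounds side by side over all 5913 genes. Of the 17 genes that rose with fluconazole 16 also rose with NT-a9, ERG24 and PGA10 among them, and of the 43 that fell 15 also fell. Independent sets of those sizes would share 7.90 and 11.3 genes. A further 9 genes fell with fluconazole and rose with NT-a9, CAR1 among them, and none did the reverse. Because 2749 of the 5913 genes rose with NT-a9, independent sets would share more than 9 such genes, so the count is no excess. The log2 fold changes correlated at r = 0.203 (rho = 0.174), with the same sign in 52.6% of genes. In 100 simulations of unchanged groups against the same controls r was 0.4998 (SD 0.0119), with the same sign in 66.7%. The simulations hold no effect, whereas NT-a9 changed 4301 genes, which alone can lower both measures. The lower values therefore do not show that the responses are less alike than unrelated ones. The covariance of the log2 fold changes was 0.0708 against 0.0170 in the simulations. With 3 controls a split with at least 2 per part was not possible, so part of the overlap may come from the shared libraries.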

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

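In this part the tests of scaling, of ribosomal RNA, of the most abundant genes and of other splits of the libraries were chosen after the results were seen. The length tests and the test without NT-a9 replicate 2 were set earlier. The patterns that they address are nevertheless results of these same libraries.

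A difference between the responses to both compounds drew attention to 9 genes that fell with fluconazole and rose with NT-a9. Independent sets of the genes that fell and rose would share more than 9, so the count itself shows no excess. Since the genes were chosen for opposite calls against the same controls, a called difference between the compounds was fixed by that choice and adds no support. The 3 of them with a symbol are CAR1, DRE2 and HAC1, of which the last 2 were named after their values were seen. CAR1, which encodes arginase, stood at 17.1 ± 3.46 FPKM in control, 8.25 ± 1.05 with fluconazole and 169 ± 36.1 with NT-a9 (SD, n = 3), and the NT-a9 effect exceeded the fluconazole effect by 4.18 on the log2 scale (limma, adjusted p = 9.71e-11). DRE2, of iron-sulfur protein assembly, stood at 9.94 ± 1.78 FPKM in control, 4.37 ± 1.31 with fluconazole and 24.2 ± 4.12 with NT-a9 (SD, n = 3), with a difference of 2.25 (limma, adjusted p = 2.26e-07). HAC1, the transcription factor of the unfolded protein response, stood at 129 ± 5.45 FPKM in control, 87.5 ± 6.95 with fluconazole and 258 ± 21.8 with NT-a9 (SD, n = 3), with a difference of 1.55 (limma, adjusted p = 3.94e-08). The fluconazole calls of CAR1, DRE2 and HAC1 held in 3, 4 and 3 of the 9 omissions of 1 library, with adjusted p up to 0.115 (CAR1, without fluconazole replicate 2), 0.147 (DRE2, without control replicate 1) and 0.198 (HAC1, without control replicate 1). With median-of-ratios scaling the opposite signs stayed, at 2.90 and -0.87 for CAR1, 0.89 and -0.96 for DRE2 and 0.67 and -0.45 for HAC1.

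Fluconazole lowered 43 genes and raised 17, so that 71.7% of calls were lower. The tables argue against ribosomal RNA, whose smaller share with fluconazole would move all other genes up by 0.050 on the log2 scale (0.0125 to 0.0999 over pairs of libraries) and not down. After the trend on coding length over all genes was removed, 96.0% of the median change of the 43 genes was left (-0.92 before and -0.89 after). That trend thus accounts for little of the size of their fall. The 43 genes were selected for falling and the calls were not recounted, so the test cannot tell whether length adds to the imbalance. Their median coding length was 732, against 1347 for the genes that rose. With median-of-ratios scaling 25 of the 43 were still called lower, between the limits of 22 and 35 set for that test, and their median change moved from -0.92 to -0.83, against a median standard error of 0.179. Coding length, the scaling of each library to its own total and a biological response to fluconazole all stay open for the imbalance. Median-of-ratios scaling centres the median gene and so tends to even out the calls by its construction.

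With NT-a9, 66 of 67 ribosomal protein genes rose while 15 of 20 sugar transport genes fell. Removing the trend on coding length left list medians of 2.06 and -1.66, median-of-ratios scaling left 1.82 and -1.92, and leaving out NT-a9 replicate 2 left 2.06 and -1.77, so the smaller of both was 1.66, 1.82 and 1.77 in size. These values argue against length, against scaling and against that single library as the whole cause. A response to the compound remains a hypothesis, found and tested on the same libraries, and it may include a difference in growth stage at 12 h, since no culture density is given.

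With NT-a9, 63.9% of calls were higher. Rescaling without the 100 most abundant genes, whose share of fragments fell from 48.0 to 36.9%, brought the higher share to 51.5%, but against fluconazole it went from 68.5 to 57.5% only, between the limits set for that test. The smaller share of those genes in the NT-a9 libraries could account for the imbalance against control, and whether it does against fluconazole stays open. The rescaling multiplies each library by a single factor and took the median gene of NT-a9 against control from 0.30 to 0.06 on the log2 scale. A fall in the share of higher calls thus followed from the drop by construction and is no separate support. These 100 genes were picked by their mean share over all 9 libraries, so part of their drop may come from that choice. Each library's own 100 highest genes took 49.3% in control and 41.3% with NT-a9. Rescaling without ribosomal RNA left 61.3%, which argues against ribosomal RNA. Whether total RNA per cell differed stays open, as the sources mention no spike-in.

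The libraries of each pair of groups make 10 splits, too few for a share under 0.05. Fluconazole against control gave 60 genes and at most 0 in the other splits, NT-a9 against control 4301 and at most 0, and NT-a9 against fluconazole 4303 and at most 0, with 1, 1 and 1 splits as large. For lists called by camera the real values and the highest others were 13 and 11, 13 and 14, and 12 and 12, with 1, 2 and 3 splits as large. Every other split mixes the groups, which leaves part of a treatment effect between its parts and puts the rest inside them, so neither set of counts tells whether chance is excluded.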

How the results depend on the processing

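The alternatives with voom, protein-coding genes, rescaling and the sphingolipid list without LIP1 were chosen after seeing the data. No named gene and no camera direction of a called list reversed, but majorities of calls did. With median-of-ratios scaling the NT-a9 calls turned to 2145 higher and 2216 lower and those of fluconazole to 28 and 27, and with quantile normalization NT-a9 gave 2127 and 2258 and NT-a9 against fluconazole 2143 and 2217. Both methods centre the genes. For NT-a9 against control 4 list majorities turned with each, with median-of-ratios scaling those given beside the figure of lists, and with quantile normalization also secreted proteases and lipases (8 and 5 to 5 and 6) but not autophagy (7 and 7). For NT-a9 against fluconazole 10 and 9 turned, with oxidative phosphorylation going from 13 and 7 to 5 and 13, osmotic stress from 6 and 2 to 3 and 7, hyphal growth from 11 and 9 to 6 and 10, secreted proteases from 8 and 4 to 6 and 7, drug efflux from 6 and 5 to 5 and 8 and copper and zinc from 4 and 3 to 3 and 5. The rest were white and opaque markers (4 and 2 to 3 and 5; not with quantile normalization), oxidative stress (14 and 12 to 8 and 15), beta-oxidation (9 and 7 to 6 and 12) and autophagy (7 and 6 to 6 and 10), each as counted with median-of-ratios scaling. The cause was not tested. For fluconazole against control, 60 genes became 162 with only the 6 libraries compared, 37 with voom on recovered fragments (36 of the 60 among them), 111 when rescaled without ribosomal RNA and 13 with a 2-fold minimum, and single omissions gave 2 (without fluconazole replicate 3) to 178 (without NT-a9 replicate 2). The fit with 6 libraries leaves out the NT-a9 libraries, which spread more; the cause was not tested further. The other settings gave 47 to 83 genes. NT-a9 against control gave 2290 genes with a 2-fold minimum and 3944 to 4273 under single omissions, and NT-a9 against fluconazole 2344 and 4042 to 4276. Gene lists called fell to 0, 0 and 0 with an estimated correlation, and fry, which asks another question, gave 2, 24 and 24. Camera calls with fluconazole ended for the proteasome with median-of-ratios scaling, for heat shock with quantile normalization and with a minimum of 10 FPKM, and for glycolysis with quantile normalization (adjusted p = 0.459). With NT-a9 those of glycolysis and gluconeogenesis also ended with a minimum of 10 FPKM, only the 6 libraries compared, the replicate block, protein-coding genes only and rescaling without the 100 most abundant genes (gluconeogenesis also with a pseudocount of 0.1), and those of glycogen and calcineurin with a minimum of 10 FPKM. Against fluconazole the sulfur call also ended when rescaled without the 100 most abundant genes and the calcineurin call with the replicate block. Calls were gained with quantile normalization for amino acid transport and DNA replication with fluconazole, for the cell wall with NT-a9 and for glycolysis and the proteasome in NT-a9 against fluconazole (adjusted p = 0.0297 and 0.0482). With fluconazole, osmotic stress, amino acid transport and glycogen were gained with a pseudocount of 5 and with voom. Single omissions also gained calls with fluconazole for osmotic stress, amino acid transport and white and opaque markers (without control replicate 1), glycogen (without control replicate 3), beta-oxidation (without control or fluconazole replicate 3) and sulfur assimilation (without fluconazole replicate 2), and for hyphal growth in NT-a9 against fluconazole (without NT-a9 replicate 1). Under single omissions 10 to 14, 10 to 13 and 10 to 13 lists were called. The correlation of both treatments ran from 0.166 to 0.234 under single omissions. Named genes lost a call in 128 alternative values for fluconazole, 2 for NT-a9 and 3 for NT-a9 against fluconazole, and the last 5 were CUP1, PRA1 and NTH1 under quantile normalization or median-of-ratios scaling.

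Replicate numbers showed no clear pairing of the libraries over the 3 groups. Deviations of same-numbered libraries correlated at -0.193 to 0.124, with 1 of 9 pairs over 0.1, other pairs at -0.0932 to 0.144, and 0 libraries correlated best with their own number in both other groups. Among fluconazole libraries, each control library correlated best with its own number (0.124, 0.0491 and 0.0168). Between control and NT-a9 the same-numbered pairs lay below 0 (-0.193, -0.0605 and -0.0845). Correlations this weak do not exclude a pairing of control and fluconazole libraries. With the replicate block 79, 4194 and 4207 genes and 13, 11 and 11 lists were called in the 3 comparisons. Depth limits genes near the floor of 0.0481 to 0.0907 FPKM (3 fragments on a gene of 1 kb), which lies higher for shorter genes.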

Other observations

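All symbol groups and single genes in this part were chosen after the data were seen, as was the test of the order of ergosterol genes.

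Of 70 groups of at least 6 tested genes whose symbols share their first 3 letters, 33 lay wholly outside the fixed lists, and in 7 of those at least 80% of genes rose with NT-a9 (10 against fluconazole), while in 0 did as many fall. With median-of-ratios scaling 5 and 5 groups reached 80% higher and 0 lower, and with quantile normalization 7 and 7 higher and 2 and 2 lower, the latter being DAL (7 of 8) and IFF (6 of 7). All 12 TIM genes, which encode the import machinery of the inner mitochondrial membrane, rose with a median of 1.25 (9 with median-of-ratios scaling, median 0.93), with TIM23 at 143 ± 24.3 against 30.1 ± 4.16 FPKM (SD, n = 3). The 6 TOM genes of the import machinery of the outer membrane rose (5 with median-of-ratios scaling), with TOM20 at 399 ± 24.6 against 60.04 ± 12.2 FPKM. TOM1, the 1 further gene of that group, fell, at 26.6 ± 2.76 against 41.8 ± 3.18 FPKM, and encodes a ubiquitin ligase that shares only the letters. All 6 CCT genes, subunits of the cytosolic chaperonin, rose (6 with median-of-ratios scaling), with CCT7 at 45.7 ± 7.57 against 9.78 ± 1.59 FPKM. All 7 URA genes of pyrimidine synthesis rose (6 with median-of-ratios scaling), with URA3 at 34.5 ± 2.56 against 4.17 ± 0.874 FPKM (SD, n = 3). None of the TIM, TOM, CCT and URA genes passed with fluconazole on the deposited scale, but 1 URA gene was higher under median-of-ratios scaling and under quantile normalization, and no enrichment test was run on groups picked this way.

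COX17, which encodes a copper chaperone of the mitochondria, differed within the control group. Its FPKM was 264, 10.6 and 318 in control replicates 1, 2 and 3, 7.38, 10.1 and 11.2 with fluconazole and 4.05, 8.82 and 4.17 with NT-a9. In fluconazole against control the genes that fell had a median coding length of 732 and those that rose 1347, against 1233 over all genes tested, and log2 fold change correlated with log2 length at r = 0.195 across genes, which are not independent replicates.

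A hypothesis was that ergosterol genes with larger changes under NT-a9 also had larger changes under fluconazole. Across the 25 genes the log2 fold changes of both compounds correlated at r = 0.475 and rho = 0.436. Of simulations with shared controls and an even shift by fluconazole, 98.95% gave a lower r and 97.9% a lower rho. Without the 2 genes highest with NT-a9 r was 0.487. The order of the genes may therefore be partly shared between the compounds, but several of these fold changes had been seen before the test was written and genes are not independent replicates.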
